A study of Saccharomyces cerevisiae W303 with 9 samples.

How the data were processed

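The data are 9 RNA-seq libraries of poly(A) RNA from yeast of the W303 background, 3 each of the wild type, an aim29 deletion and the aim29 deletion with pmTDH3-ZPR1. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, 3 isolates per strain were grown to mid-log phase, 1 optical density unit of cells was collected by centrifugation, and a sequencing company extracted the RNA and made libraries with standard Illumina methods. The deposited file is a table of raw counts, whole numbers per annotated feature and library, which the authors did not normalise. FastQC 0.11.5, STAR 2.7.0, DESeq2 1.34.0 and genome build R64 are named in the submitters' processing notes. The counting tool, the strand setting, the treatment of reads that map to several places and the read length are not given in the sources used here. Values of overlapping or antisense genes and of genes with near-identical copies are therefore uncertain.

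The table holds 7127 features, of which 393 had 0 counts in all libraries. Of the features, 6047 were matched by locus tag and 122 by symbol to the reference annotation of build R64, from which positions are given; 958 were not matched. The tRNA features were not matched by name, and tK(UUU)K was placed as the only lysine tRNA gene with its anticodon on chromosome XI. The share of 50-base windows of a gene that occur once in the genome was computed from the reference sequence as a measure of shared reads. Total counts ran from 14380639 to 20140071, and 3 counts correspond to 0.143 to 0.213 CPM.

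Genes were filtered with filterByExpr, which kept 5970, and tested with edgeR 4.0.16 (TMM factors, glmQLFit and glmQLFTest) in R 4.3.3 on the counts as deposited, in a fit of all 9 libraries with the group as the only term and 6 residual degrees of freedom. The 3 comparisons are the deletion against the wild type, the construct strain against the deletion, and the construct strain against the wild type. P-values were adjusted with the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. Log2 fold changes carry the standard error from the fit, and CPM values the SD of 3 libraries. CPM were computed with TMM-scaled library sizes, and a prior count of 2 was added on the log scale. Gene lists, 38 in number, were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and the 114 p-values of the lists and comparisons were adjusted together; the same test was run with an estimated correlation. Lists of genes were also adjusted over the list alone.

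The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. Named genes are AIM29, ZPR1, TEF1, TEF2, TDH3 and 3 protein-coding neighbours on each side of AIM29 and ZPR1; per comparison up to 10 genes with the largest rise and 10 with the largest fall among called genes with a mean of at least 10 CPM and no overlap between groups; and per called list up to 4 members with the lowest p, or 2 where none was called. Features named outside this rule were chosen after their values were seen. Not all genes that meet the rule are reported here.

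Replicate libraries were compared by a chi-square test of their counts, and each pair differed by more than sampling noise (chi-square per degree of freedom 2.93 to 65.7), so no library was counted as a copy of another. Correlations between comparisons that share libraries were set beside 20 simulations of unchanged groups, drawn with 1 spread per gene shared by the groups. The procedure was tested on simulated data, with counts drawn from the wild-type means, the library sizes and 1 spread for all genes of a group. In the deletion group 200 genes of at least 10 CPM were changed. Spread that differs between genes was not simulated, so recovery and false calls may be less favourable in the real data. For the deletion against the wild type it recovered 97 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold among 5946 genes tested, with 0 false calls. For the construct strain against the deletion it recovered 84 and 100 of 100, with 21 false calls among 205. Over 10 further simulations false calls made up 10.2% of the calls of this comparison and 0.0516% of those of the deletion against the wild type; with limma-voom and library quality weights the shares were 6.68% and 5.03%. The fit shares 1 estimate of the spread among groups that differ in it.

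Alternatives were median-ratio factors, no composition factors, no low-count filter, a filter of at least 100 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the groups compared alone, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, a log2 fold change of at least 1, an estimated correlation for camera, and an Hsf1 list extended by other chaperones. Library quality weights and the rotation test fry were added after seeing the data. Annotation and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.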

Results

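Poly(A) RNA of budding yeast of the W303 laboratory background was sequenced in 9 libraries that fall into 3 groups of 3. The groups are the wild type, a strain lacking AIM29 (the deletion strain), and the deletion strain carrying the construct pmTDH3-ZPR1 (the construct strain). The labels do not spell out the first letters of the construct's name; TDH3 is a highly transcribed glycolytic gene, and Zpr1 is a zinc finger protein known as a folding chaperone for the translation elongation factor eEF1A. Per the labels' growth protocol, the 3 libraries of a group are separate isolates of a strain, grown in rich glucose medium to an optical density at 600 nm of 0.4 to 0.6. The deposited table holds read counts for 7127 annotated features. Totals were 17140665, 15601784 and 15983507 counts in the wild-type libraries, 14483924, 14380639 and 14586083 in the deletion libraries, and 18044486, 20140071 and 18793582 in the construct libraries, so the ranges of the 3 groups did not overlap. Of these features, 5970 had enough counts to be tested. Variation among libraries of a group, as a biological coefficient of variation, was 5.23% in the wild type, 3.78% in the deletion strain and 14.7% in the construct strain, where it was 10.04% without replicate 3.

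The genes named in the labels were examined before the comparisons. AIM29 (YKR074W, chromosome XI, 579209 to 579676 on the plus strand, build R64, a single annotated exon) had 78.4 ± 3.38 CPM (read counts scaled to library size; SD, n = 3) in the wild type, 2.76 ± 1.72 in the deletion strain and 6.56 ± 1.22 in the construct strain. Reads on AIM29 were thus at 3.52% of the wild-type level in the deletion strain and at 8.37% in the construct strain. The source of these remaining reads was not tested. AIM29 was lower in all libraries of both strains than in any wild-type library. The fitted log2 fold changes from the wild type were −4.82 ± 0.31 (SE) and −3.58 ± 0.27, with adjusted p of 8.2e-06 and 0.000161 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ZPR1 (YGR211W, chromosome VII, 915241 to 916701 on the plus strand) had 329 ± 7.59 CPM in the wild type, 422 ± 22.6 in the deletion strain and 5380 ± 454 in the construct strain. It was 12.8-fold higher in the construct strain than in the deletion strain and 16.3-fold higher than in the wild type. In the deletion strain ZPR1 itself was 1.28-fold higher than in the wild type (log2 fold change 0.36 ± 0.07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0121).

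**Figure D1:**
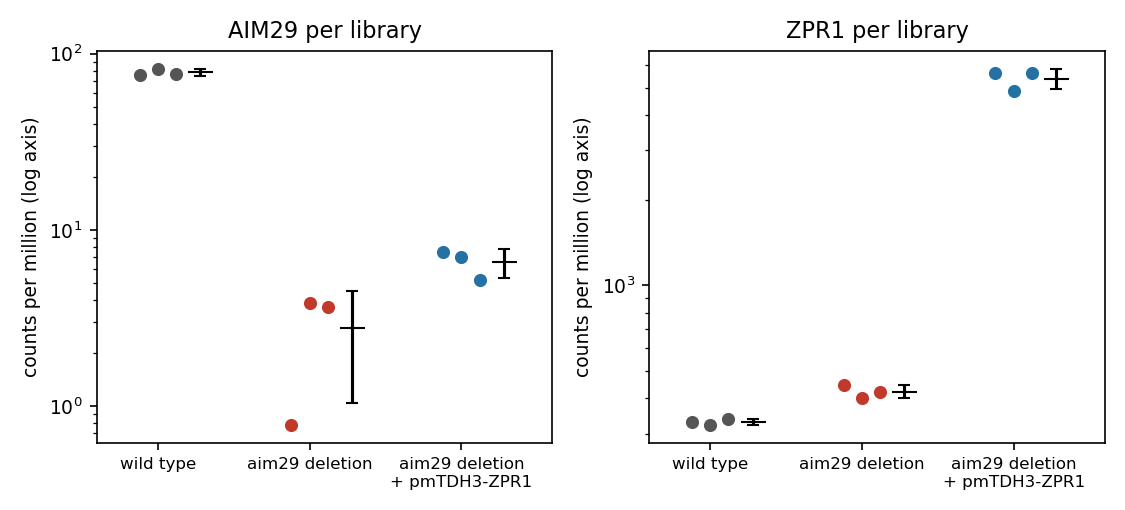
CPM of AIM29 (left) and ZPR1 (right) on log axes, 1 point per library in the wild type, the aim29 deletion and the aim29 deletion with pmTDH3-ZPR1; the black bar and whiskers beside each group are the mean and SD of 3 libraries. AIM29 fell from a mean of 78.4 in the wild type to 2.76 and 6.56, and ZPR1 was at 329, 422 and 5380.

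The comparison of the deletion strain with the wild type asks which transcripts differ when AIM29 is missing. Targets of the heat shock factor Hsf1 and amino acid synthesis genes were higher in the deletion strain, and genes of the G1/S transition of the cell cycle were lower. These lists were called by camera with its preset correlation, but not with an estimated one. HSP82, which encodes an Hsp90 chaperone, was at 754 ± 53.5 CPM (SD, n = 3) in the deletion strain and 186 ± 19.9 in the wild type, a 4.06-fold difference. SSA1, an Hsp70 gene, was 3.20-fold higher. The zinc transporter gene ZRT1 was 2.87-fold lower, at 108 ± 9.39 CPM against 309 ± 61.4.

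In total 253 genes were higher and 129 lower in the deletion strain by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, among 5970 tested, and 41 and 8 of them differed at least 2-fold. The values of the 3 deletion libraries lay wholly above or below those of the 3 wild-type libraries in 40.4% of tested genes, where chance gives 10%. Falls and rises were ranked among called genes with a mean of at least 10 CPM. After AIM29, the largest of these falls were in ZRT1 (log2 fold change −1.52 ± 0.19, SE), the acid phosphatase gene PHO5 (−1.17 ± 0.29), the cell adhesion gene AGA1 (−1.08 ± 0.23) and the purine synthesis gene ADE17 (−0.98 ± 0.21). They were followed by MIP6 (−0.96 ± 0.17), IZH4 (−0.94 ± 0.19), the a-factor gene MFA1 (−0.91 ± 0.20) and the repressor gene YOX1 (−0.79 ± 0.10). YJR029W, at −1.21 ± 0.15, has no 50-base window that is unique in the genome, so its reads cannot be assigned to this copy. Among the largest rises were ARO5 (2.79 ± 0.22), BSC5 (2.25 ± 0.09), YNR068C (2.09 ± 0.13), HSP82 (2.02 ± 0.19), the autophagy gene ATG41 (1.92 ± 0.21), SPO24 (1.91 ± 0.27), BTN2 (1.88 ± 0.17), CUR1 (1.69 ± 0.20) and SSA1 (1.68 ± 0.09). BTN2 and CUR1 encode factors that sort misfolded proteins. ATG41, also named ICY2, is a member of the amino acid synthesis list described below.

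Targets of Hsf1, the transcription factor of the heat shock response, rose together. All 18 members of this list passed the test over all genes, and all 18 also adjusted over the list alone, with fold changes between 0.56 and 2.02 on the log2 scale and a median of 1.08. The Hsp90 co-chaperone gene STI1 rose by 1.14 ± 0.06, SSA2 by 1.01 ± 0.06 and HSC82 by 0.83 ± 0.05. SSA1 and SSA2 share most of their sequence, with 42.1% of their 50-base windows unique, so their separate values are uncertain, as are to a lesser degree those of HSP82 and HSC82 (93.6% for HSP82). The camera test gave the list an adjusted p of 2.03e-34 with its preset correlation of 0.01 and an adjusted p of 0.0827 with an estimated correlation. Among 22 other chaperone and heat shock genes, 7 rose (8 adjusted over the list alone), among them SGT2 (0.60 ± 0.04), the Hsp110 gene SSE1 (0.60 ± 0.05), the J-protein gene APJ1 (1.10 ± 0.12) and OPI10 (0.75 ± 0.11). Their median was 0.20 (camera adjusted p = 8.33e-06, and adjusted p = 0.0827 with an estimated correlation). Of 32 proteasome subunit genes, 10 rose (23 adjusted over the list alone), with SCL1 at 0.34 ± 0.05 and PUP3 at 0.28 ± 0.05, a median of 0.17 and an adjusted p of 0.457 with an estimated correlation. In the ubiquitin pathway 6 of 25 genes rose (11 adjusted over the list alone), including RPN4 (0.76 ± 0.11), which encodes the transcription factor of proteasome genes, and the conjugating enzyme genes UBC4 (0.26 ± 0.04) and UBC5 (0.49 ± 0.09). The list had an adjusted p of 0.234 with an estimated correlation. The 36 genes of the general stress response driven by Msn2 and Msn4 held 0 called genes by edgeR or DESeq2 and 1 with an unadjusted p under 0.05, and had a median of −0.05 (camera adjusted p = 0.774).

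Amino acid synthesis genes controlled by Gcn4 were the other large set. Of 46 genes, 35 rose and none fell over all genes tested, and 41 rose adjusted over the list alone; the median was 0.66. HIS5, of histidine synthesis, rose 2.01-fold and the cyclin gene PCL5 2.42-fold. The log2 fold changes were 1.13 ± 0.11 for the ornithine transporter gene ORT1 and 0.59 ± 0.06 for TRP2. The camera adjusted p was 1.88e-35, and the adjusted p was 0.16 with an estimated correlation. In the methionine and sulfur list 4 of 23 genes rose (12 higher and 2 lower adjusted over the list alone), among them MET22 (0.61 ± 0.11) and STR3 (1.17 ± 0.21), with an adjusted p of 0.618 with an estimated correlation.

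G1/S genes fell, 8 of 11 over all genes and 10 adjusted over the list alone. The G1 cyclin gene CLN1 was at −0.68 ± 0.08, RNR1, a ribonucleotide reductase subunit gene, at −0.51 ± 0.07, the cyclin gene CLB5 at −0.42 ± 0.06 and the polymerase gene POL1 at −0.42 ± 0.07. The list median was −0.42 (camera adjusted p = 3.59e-10, and adjusted p = 0.091 with an estimated correlation). Of 10 DNA damage genes RNR1 alone fell (4 adjusted over the list alone), and the list had an adjusted p of 0.16 with an estimated correlation. Among 18 pheromone response genes FAR1 (−0.58 ± 0.05), AGA1 and STE4 (−0.20 ± 0.05) fell, and among 7 a-specific genes BAR1 (−0.76 ± 0.14) and MFA1 fell. Adjusted over the list alone 4 and 5 genes fell, and these lists had adjusted p of 0.638 and 0.481 with an estimated correlation.

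Lists of the translation machinery moved by small amounts. Of 137 ribosomal protein genes 13 rose (14 adjusted over the list alone), with RPS21A at 0.38 ± 0.06 and RPS30A at 0.30 ± 0.05, and the median was 0.09 (adjusted p = 0.638 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes 6 fell (19 adjusted over the list alone), with MRPS35 at −0.40 ± 0.07, MRPS28 at −0.36 ± 0.09 and a median of −0.20 (adjusted p = 0.589 with an estimated correlation). Of 75 ribosome biogenesis genes NUG1 (−0.28 ± 0.05), RLP24 (−0.24 ± 0.06) and NOP16 (−0.20 ± 0.05) fell, and 1 gene adjusted over the list alone, with a median of −0.15 (adjusted p = 0.618 with an estimated correlation). Among 28 initiation factor genes edgeR called SUI2 alone (−0.20 ± 0.05), and 0 adjusted over the list alone, while DESeq2 called 2 and 8 had an unadjusted p under 0.05 by edgeR, with an adjusted p of 0.613 for the list with an estimated correlation. The genes for eEF1A, TEF1 and TEF2, were not called, at −0.08 ± 0.05 and 0.13 ± 0.06; only 7.53% of the 50-base windows of each are unique, so most reads of this pair cannot be told apart. The 11 elongation factor genes tested had a median of −0.04, with 0 called by edgeR or DESeq2 and 2 with an unadjusted p under 0.05 (camera adjusted p = 0.222).

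In the remaining lists with a camera call, ZRT1, ZRT2 (−0.32 ± 0.06) and MCD4 (−0.38 ± 0.09) fell among 13 zinc-regulated genes, PHO5 and PHO11 (−0.62 ± 0.13) among 16 phosphate-regulated genes and DIT1 (−0.48 ± 0.12) among 15 meiosis and sporulation genes. RTG3 (0.29 ± 0.07) and IDH2 (0.32 ± 0.07) rose among 16 genes of the tricarboxylic acid cycle and retrograde response. Of the 37 oxidative phosphorylation genes 0 were called by edgeR, 1 was by DESeq2 and 7 had an unadjusted p under 0.05, with COX7 at 0.41 ± 0.12 and QCR7 at 0.27 ± 0.09. Adjusted over the list alone, 4, 6 and 2 genes of the zinc, phosphate and meiosis lists fell and 3 of the tricarboxylic acid list rose. Adjusted p for these 5 lists, oxidative phosphorylation included, were 0.613, 0.589, 0.371, 0.676 and 0.695 with an estimated correlation. PHO11 shares its reads, as 11.7% of its 50-base windows are unique. In all, 19 of 38 lists were called by camera, 9 of them higher and 10 lower, and 0 with an estimated correlation, where 7 lists had an unadjusted p under 0.05. The fry test, which does not compare a list with other genes, called 8.

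Several settings moved the gene counts by more than 1.5 times. A fit of these 6 libraries alone called 837 genes higher and 751 lower, all 382 genes above among them. Without composition factors 187 were higher and 316 lower, a share of 37.2% higher against 66.2%. Leaving out any wild-type or deletion library lowered the counts, to 122 higher without wild-type replicate 3 and 40 lower without deletion replicate 2, and leaving out construct replicate 2 or 3 raised them, to 397 and 241 or to 577 and 520.

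**Figure D2:**
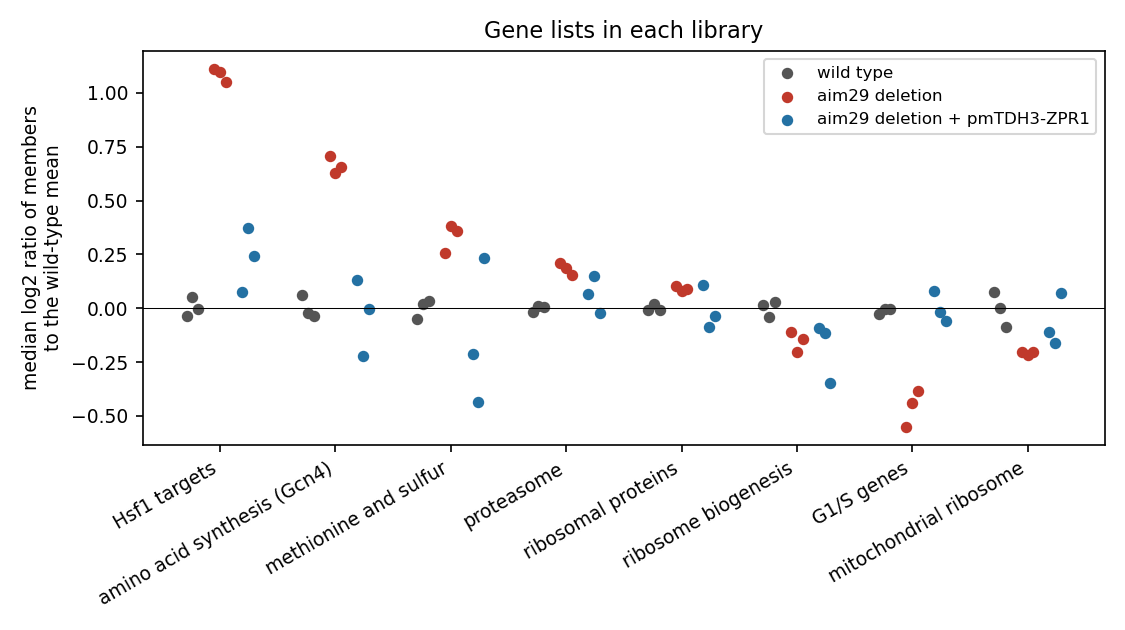
Median log2 ratio of the members of 8 gene lists to their wild-type mean, 1 point per library and colours by group. Hsf1 targets had medians of 1.08 in the fit of the deletion strain and 0.28 in that of the construct strain against the wild type, while the amino acid synthesis list had 0.66 and −0.01.

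The comparison of the construct strain with the deletion strain asks what differs when ZPR1 is raised in the absence of AIM29. Many genes that had changed in the deletion strain moved the opposite way, and ZPR1 was the gene with the largest rise. HSP82 was at 258 ± 83.6 CPM (SD, n = 3) in the construct strain, 2.93-fold below the deletion strain, and SSA1 was 2.62-fold lower. ZRT1, at 262 ± 73.0 CPM, was 2.43-fold higher than in the deletion strain. By edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 99 genes were higher and 222 lower in the construct strain, 6 and 35 of them at least 2-fold. The groups did not overlap in 25.7% of tested genes, against 10% by chance.

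Among the largest falls were ARO5 (log2 fold change −2.62 ± 0.21, SE), BSC5 (−2.35 ± 0.09), YNR068C (−2.19 ± 0.13), ATG41 (−1.69 ± 0.21), HSP82 (−1.55 ± 0.18), STR3 (−1.50 ± 0.22), the arginine synthesis gene ARG4 (−1.48 ± 0.22), BNA1 of NAD synthesis (−1.47 ± 0.14) and SSA1 (−1.39 ± 0.09). Rises were ranked among called genes with a mean of at least 10 CPM. After ZPR1 (3.67 ± 0.08) the largest of these were in ZRT1 (1.28 ± 0.19), the malate dehydrogenase gene MDH2 (1.10 ± 0.17), AGA1 (0.91 ± 0.23) and IZH4 (0.86 ± 0.19). They were followed by SVS1 (0.79 ± 0.12), YOX1 (0.77 ± 0.10), DPC29 (0.76 ± 0.18), the G1 cyclin gene CLN2 (0.76 ± 0.11) and VPS71 (0.74 ± 0.17).

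Of the 18 Hsf1 targets 17 fell, over all genes and adjusted over the list alone, with a median of −0.84. STI1 was at −0.86 ± 0.06 and HSC82 at −0.75 ± 0.05. The camera adjusted p was 7.99e-28, and the adjusted p was 0.0827 with an estimated correlation. Of the other chaperone genes 6 of 22 fell (7 adjusted over the list alone), among them SGT2 (−0.57 ± 0.04), SSE1 (−0.59 ± 0.05) and CPR1 (−0.63 ± 0.09), with an adjusted p of 0.091 with an estimated correlation. The proteasome genes PUP3 (−0.22 ± 0.05) and RPN8 (−0.24 ± 0.06) fell, and 6 adjusted over the list alone, and in the ubiquitin pathway 4 genes fell, among them UBC4 (−0.22 ± 0.04) and RPN4 (−0.44 ± 0.11). These lists had adjusted p of 0.618 and 0.589 with an estimated correlation. Of the 46 amino acid synthesis genes 37 fell (42 adjusted over the list alone), with a median of −0.66, HIS5 at −1.02 ± 0.07 and PCL5 at −1.30 ± 0.11 (adjusted p = 0.16 with an estimated correlation). In the methionine and sulfur list 8 of 23 genes fell (15 adjusted over the list alone), among them MET22 (−0.71 ± 0.11) and MET6 (−0.47 ± 0.10), with an adjusted p of 0.521 with an estimated correlation. Construct replicate 3 lay a median of 0.46 above the other construct libraries over these genes, with a list median of 0.23 against the wild-type mean, near the 0.26 to 0.38 of the deletion libraries.

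Of the 11 G1/S genes 7 rose (10 adjusted over the list alone), with PCL1 at 0.66 ± 0.07, CLN1 at 0.55 ± 0.08 and a median of 0.50 (adjusted p = 0.091 with an estimated correlation). Of 10 DNA damage genes RNR1 (0.50 ± 0.07), DUN1 (0.34 ± 0.07) and RNR2 (0.25 ± 0.05) rose (4 adjusted over the list alone), also with an adjusted p of 0.091 with an estimated correlation. Of 10 histone genes 4 rose (5 adjusted over the list alone), HHF2 by 0.36 ± 0.06 and HHO1 by 0.40 ± 0.09. Of 17 unfolded protein response genes 4 rose (7 higher and 1 lower adjusted over the list alone), among them JEM1 (0.34 ± 0.07) and INO1 (1.03 ± 0.23). These lists had adjusted p of 0.371 and 0.589 with an estimated correlation. Of 137 ribosomal protein genes 9 fell (17 adjusted over the list alone), with RPL23B at −0.30 ± 0.06. The list medians against the wild-type mean were 0.11, −0.09 and −0.04 in construct replicates 1, 2 and 3 and 0.10, 0.08 and 0.09 in the deletion libraries, so replicate 1 showed no fall. Among the mitochondrial ribosomal proteins edgeR called MRPL28 higher (0.31 ± 0.07) over all genes but 0 genes adjusted over that list alone, where DESeq2 called 2 and 16 had an unadjusted p under 0.05 by edgeR. The ribosomal and mitochondrial ribosomal lists had an adjusted p of 0.618 with an estimated correlation. The mitochondrial genes COX1 (−0.71 ± 0.15) and OLI1 (−0.73 ± 0.17) fell, in a poly(A) preparation in which mitochondrial reads were at most 0.0218% of the counts of any library, and their list had an adjusted p of 0.613 with an estimated correlation. Camera also called the Msn2 and Msn4 list higher (median 0.32), the cell wall list higher (0.29), initiation factors higher (0.04) and oxidative phosphorylation lower (−0.11), with 0 members called by edgeR and adjusted p of 0.638, 0.724, 0.676 and 0.724 with an estimated correlation. In these lists DESeq2 called 9, 1, 0 and 3 genes, and 16, 7, 4 and 10 had an unadjusted p under 0.05 by edgeR. Adjusted over the list alone, 9 higher and 1 lower were called in the Msn2 and Msn4 list and 0 in the others. TSL1 of the stress list was at 0.53 ± 0.14 and CRH1 of the cell wall list at 0.44 ± 0.16. Replicate 3 stood apart here, 0.45 above the other construct libraries in the median of the Msn2 and Msn4 list and 0.72 above them in that of the cell wall list. For oxidative phosphorylation the medians of construct replicates 1, 2 and 3 against the wild-type mean were −0.16, 0.02 and 0.18 and those of the deletion libraries 0.09, 0.17 and 0.13, so replicate 3 went against the call. For initiation factors construct replicates 1, 2 and 3 were at 0.02, −0.06 and −0.07. The deletion libraries were at −0.07, −0.13 and −0.07 in that list, so replicate 3 showed no rise. In all, 17 lists were called by camera, 8 higher and 9 lower, and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. The fry test, which does not compare a list with other genes, called 7.

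Of the 253 genes higher in the deletion strain, 158 (62.5%) were called lower with the construct, and of the 129 lower ones 53 (41.1%) were called higher. Independent lists of these sizes would share 9.41 and 2.14 genes. Both comparisons use the same deletion libraries. Across genes, which are not independent replicates, the fold changes of the 2 comparisons had a Pearson correlation of −0.68, against a mean of −0.52 over 20 simulations of unchanged groups; the covariances were −0.0540 and −0.0136, a difference of −0.0404. The simulations drew all groups with 1 spread per gene, although the shared deletion libraries varied least (3.78%) and the construct libraries most (14.7%). The simulated correlation and covariance may therefore be too strong for these data. Part of the excess of shared calls may still come from the shared deletion libraries, since 3 cannot be split with 2 on each side.

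**Figure D3:**
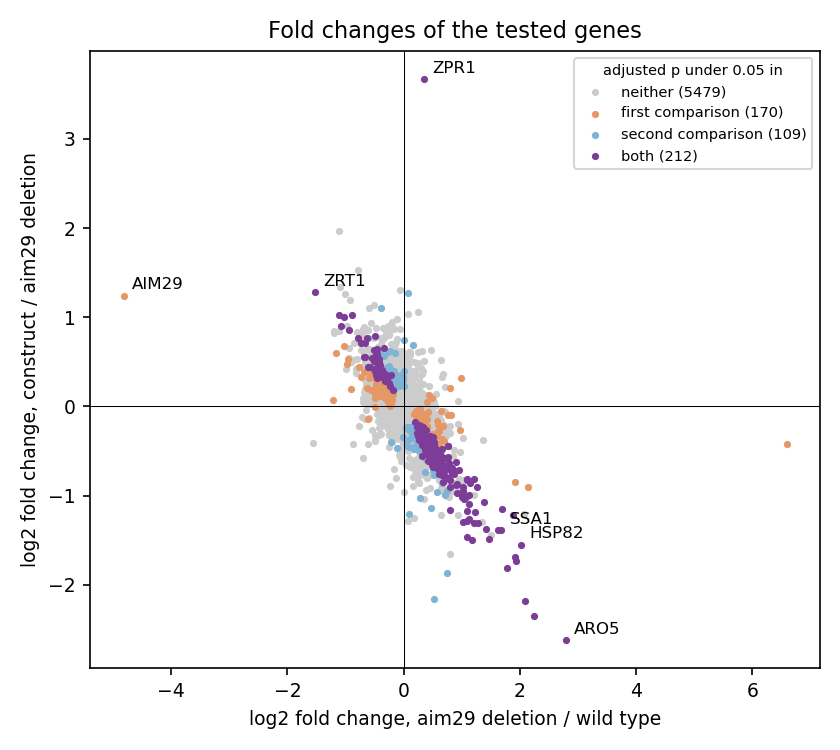
Log2 fold change of the deletion strain over the wild type (horizontal axis) against that of the construct strain over the deletion strain (vertical axis), 1 point for each of 5970 tested genes, coloured by the comparison in which its adjusted p was under 0.05. The genes called in both run from the upper left (ZRT1) to the lower right (ARO5), and ZPR1 lies above them at 3.67.

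The counts of this comparison rest on construct libraries that differ more among themselves than the others do. In data simulated with 1 spread for all genes of a group, 10.2% of the calls of this comparison were false over 10 simulations. That is above the 5% set by the adjustment, which the shared estimate of the spread allows. A fit of the 6 libraries alone called 30 genes higher and 123 lower, the fit without composition factors 196 and 181 (52.0% higher against 30.8%). Leaving out 1 library gave from 31 higher and 114 lower (without deletion replicate 2) to 312 and 408 (without construct replicate 2), with 40 and 139 without deletion replicate 1, 37 and 127 without deletion replicate 3, 151 and 266 without construct replicate 1 and 180 and 340 without construct replicate 3.

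The comparison of the construct strain with the wild type asks what remained different when ZPR1 was raised in the strain without AIM29. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 7 genes were higher and 4 lower, while 764 of 5970 had an unadjusted p under 0.05 and the groups did not overlap in 16.4% of genes, against 10% by chance. ZPR1 was higher by 4.03 ± 0.08 on the log2 scale (SE, 3 libraries per group). Further rises were in MTH1, a regulator of glucose transporter genes (1.01 ± 0.12), CIT2, the peroxisomal citrate synthase gene (0.85 ± 0.12), the glycerol synthesis gene GPD1 (0.57 ± 0.09) and SOL1 (0.54 ± 0.09). MTH1 had 22.8 ± 1.78 CPM (SD, n = 3) in the wild type, 39.7 ± 1.39 in the deletion strain and 45.7 ± 8.29 in the construct strain, whereas CIT2 had 33.9 ± 2.64, 38.0 ± 4.80 and 61.0 ± 8.77. The falls were in AIM29, PHO11 (−0.76 ± 0.12), YJR029W (−1.14 ± 0.15) and YMR050C (−0.62 ± 0.09); the latter pair have no unique 50-base window, and PHO11 shares most of its sequence with other genes.

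The other higher features lie beside AIM29. YKR075C (chromosome XI, 579827 to 580750, minus strand), the next gene downstream, had 6.18 ± 0.146 CPM (SD, n = 3) in the wild type, 12.2 ± 0.353 in the deletion strain and 15.1 ± 1.73 in the construct strain. The lysine tRNA feature tK(UUU)K, named here after its values were seen, corresponds to the only lysine tRNA gene with anticodon UUU on chromosome XI (578965 to 579060, plus strand), 148 bases upstream of AIM29. It had 4 counts over the 3 wild-type libraries, 362 over the deletion libraries and 366 over the construct libraries, ratios of 105 (95% counting interval 40.8 to 388) and 79.2 (30.7 to 292) after scaling to library size. These intervals cover counting error only. The gene on the other side, YKR073C, did not pass the test in either strain, at 1.01 ± 0.30 and 0.66 ± 0.30. MSA2, further downstream, was lower in the deletion strain (−0.46 ± 0.08, adjusted p = 0.00599) and not called against the wild type in the construct strain (0.19 ± 0.08).

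**Figure D4:**
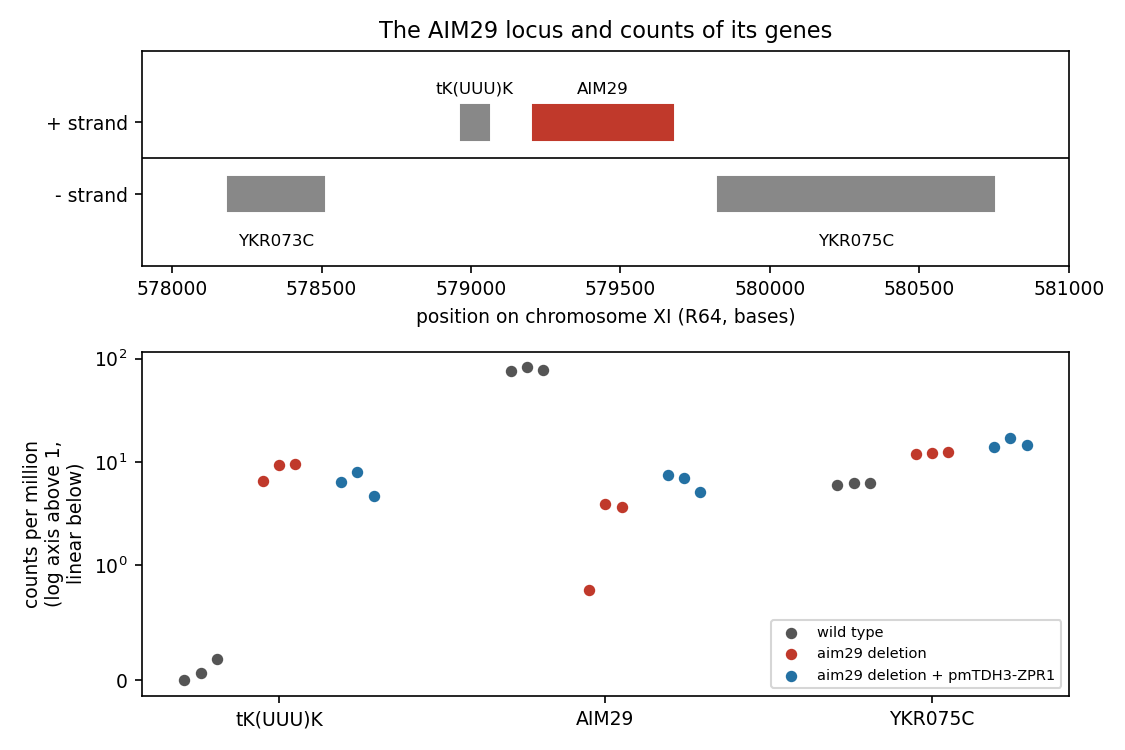
Map of the AIM29 locus on chromosome XI (top, build R64, positions in bases, boxes to scale on their strand) and CPM of 3 of its features in each library (bottom, log axis above 1 and linear below). AIM29 was near 78.4 in the wild type, and tK(UUU)K and YKR075C were higher in both strains without AIM29 than in any wild-type library.

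Of the 382 genes changed in the deletion strain, 5 of the higher and 3 of the lower genes were also called against the wild type in the construct strain. The 5 were ZPR1, which the construct raised, tK(UUU)K and YKR075C beside AIM29, MTH1 and GPD1. The 3 were the deleted gene AIM29, and PHO11 and YJR029W, which share reads with other genes. The median log2 difference of all 253 and 129 genes from the wild type was 0.07 and −0.09, where it had been 0.51 and −0.41 in the deletion strain. The 95% interval of the difference excluded 50% or more of the deletion change in 113 of the 253 higher and 30 of the 129 lower genes. It excluded 0 in the direction of the deletion in 68 of the 382 genes, 8 of them among those 143. It lay wholly above 50% in 9, which are IMA1 and the genes called in both strains, ZPR1 and AIM29 included. In 179 genes it reached from 0 or below to 50% or above, so what remained was left open. These intervals use 1 estimate of the spread for all groups, although the construct libraries vary most, so they may be too narrow. The wild-type libraries used to call the genes are also the baseline here, which favours a difference in the direction of the deletion. The 18 Hsf1 targets had a median of 0.28, with 0 called over all genes by edgeR, 3 by DESeq2, 11 at an unadjusted p under 0.05 and 11 higher adjusted over the list alone (camera adjusted p = 1.45e-10, and adjusted p = 0.192 with an estimated correlation). STI1 was at 0.28 ± 0.06 and MDJ1 at 0.27 ± 0.07. The amino acid synthesis list had a median of −0.01, with 0 members called by edgeR or DESeq2 and 0 with an unadjusted p under 0.05 (camera adjusted p = 0.276), and the G1/S list a median of −0.01 (0.86).

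Camera called 18 lists, 10 higher and 8 lower, and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05. The fry test, which does not compare a list with other genes, called 3. Over all genes edgeR called a member in only a few of them, CIT2 in the tricarboxylic acid cycle and retrograde list and PHO11 in the phosphate list. Adjusted over the list alone, 23 of 75 ribosome biogenesis genes were lower (median −0.18, adjusted p = 0.521 with an estimated correlation), 8 of 10 histone genes higher (0.19, adjusted p = 0.16 with an estimated correlation) and 11 of 16 phosphate-regulated genes lower (−0.28, adjusted p = 0.16 with an estimated correlation). NUG1 was at −0.22 ± 0.05, HTA2 at 0.28 ± 0.05 and HHF2 at 0.31 ± 0.06. The proteasome (0.06), ubiquitin (0.04), Msn2 and Msn4 (0.27), glycolysis (0.10), drug resistance (0.24), cell wall (0.28) and mitotic (0.16) lists were also called higher, and the mitochondrial ribosomal (−0.05), methionine (−0.08), purine (−0.20), ergosterol (−0.09), zinc (−0.08) and a-specific (−0.21) lists lower, with adjusted p from 0.509 to 0.764 with an estimated correlation. Replicate 3 stood apart in several of these lists. The medians of replicates 1, 2 and 3 were −0.04, 0.01 and 0.71 in the cell wall list, −0.05, 0.21 and 0.47 in the Msn2 and Msn4 list, −0.03, −0.09 and −0.48 in the purine list, −0.05, 0.04 and −0.29 in the ergosterol list and −0.09, −0.12 and −0.35 in the ribosome biogenesis list. In the methionine list they were −0.21, −0.44 and 0.23 and in the mitochondrial ribosomal list −0.11, −0.16 and 0.07, so replicate 3 went against the call. Proteasome replicate 3 and glycolysis replicate 2, both at −0.02, also went against their calls. In the tricarboxylic acid cycle and retrograde list replicates 1, 2 and 3 were at −0.01, 0.06 and 0.30, so replicate 1 showed no rise. In the drug resistance list the construct libraries were at 0.21, 0.30 and 0.34. Wild-type replicates 1, 2 and 3 were at −0.48, 0.26 and 0.23 there, so that call rests on wild-type replicate 1.

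The number of genes called against the wild type depended on single libraries. It was 39 higher and 33 lower with DESeq2, 33 and 40 without construct replicate 1, 28 and 13 without replicate 2, 26 and 37 without replicate 3. It was 3 and 1 without wild-type replicate 1 or replicate 3, 3 and 2 without wild-type replicate 2, 4 and 2 without deletion replicate 1 or replicate 3, 5 and 2 without deletion replicate 2, and 3 and 1 in a fit of the 6 libraries alone.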

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

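Library quality weights and fry were chosen after seeing the data; the other alternatives were not. Of the 298 values recomputed for the results that answer a comparison, 201 stayed within 1.5 times or kept their call, 94 moved and 3 fell below the threshold; the cause was not tested unless stated. The log2 fold change of no called gene changed sign in any setting that tested the gene. The log2 fold changes of AIM29 (−5.14 to −4.38) and ZPR1 (3.64 to 3.74) stayed called when single libraries were left out. The Hsf1 medians of 1.08, −0.84 and 0.28 kept direction and call in all alternatives run except an estimated correlation, where adjusted p were 0.0827, 0.0827 and 0.192; by fry they were 0.000123, 0.000164 and 0.0441, and with other chaperones added the medians were 0.60, −0.52 and 0.10. With an estimated correlation 0 of 19, 17 and 18 called lists remained; without single libraries the numbers were 17 to 20, 17 to 19 and 13 to 19.

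For the deletion against the wild type (253 higher, 129 lower), the fit of the 2 groups alone called 837 and 751, quality weights 827 and 736, and both called all 382 genes again. DESeq2 called 365 and 232, no composition factors 187 and 316, an adjusted p under 0.01 called 123 and 40, and a log2 fold change of at least 1 left 41 and 8, the latter by construction. For the construct strain against the deletion (99 and 222), the 2 groups alone gave 30 and 123, quality weights 233 and 388, DESeq2 195 and 308, no composition factors 196 and 181, the lower p 30 and 113 and the fold limit 6 and 35. Against the wild type (7 and 4) the same settings gave 3 and 1, 25 and 15, 39 and 33, 6 and 5, 4 and 1, and 4 and 2. Shared calls (158 and 53) were 332 and 173 with quality weights, 217 and 89 with DESeq2 and 131 and 112 without composition factors. The quality weights of the construct libraries were 1.25, 0.34 and 0.17 for replicates 1, 2 and 3. Without composition factors the median of all genes moved by less than 0.1 in each comparison; in the deletion against the wild type the medians of the CCT and prefoldin, glycolysis, cell wall, histone and mitotic lists, none of them called, changed sign.

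Leaving out single libraries gave 122 to 577 higher and 40 to 520 lower genes in the deletion, 31 to 312 and 114 to 408 for the construct strain against the deletion, and 3 to 33 and 1 to 40 against the wild type. Shared calls ran from 96 to 265 and from 20 to 131. Where a library was left out its group has 2 libraries. Leaving out a wild-type or deletion library lowered the counts of the deletion, while leaving out any construct library raised the counts of all 3 comparisons; the cause was not tested.

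With the replicate number as a block, 232 and 96 genes were called for the deletion, 206 lower and 75 higher for the construct strain against the deletion and 6 and 5 against the wild type. The numbers do not pair the libraries: correlations of same-numbered libraries ran from −0.107 to 0.0745, none of 9 above 0.1, and 1 of 9 libraries correlated best with its own number.

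Direction changed in 15 values of genes next to AIM29 or ZPR1, none of them called. RPS0A was at −0.0043 without composition factors in the deletion. With quality weights SIS2 was at 0.0142 and ECM4 at −0.00965 against the deletion, and against the wild type SIS2 was at 0.0815, ECM4 at −0.202, SER2 at 0.0636 and RPS0A at 0.0365. Without single libraries SIS2 ran from −0.210 to 0.0146 and ECM4 from −0.153 to 0.652 against the deletion. Against the wild type SIS2 ran from −0.137 to 0.0872, ECM4 from −0.361 to 0.443, SER2 from −0.0715 to 0.0563, RTA1 from −0.142 to 0.248 and RPS0A from −0.112 to 0.0334. Of the other values of named genes, 379 of called genes no longer passed the threshold, 105 of uncalled genes now passed it, and 2177 and 1352 kept their side.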

Other observations

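The tests on the construct strain and on the AIM29 locus in this part were chosen only after the results were seen, and the counts over other splits of the libraries were not. In the deletion strain several gene groups that bear on growth were not called as lists by camera. The 15 genes of the CCT chaperonin and prefoldin, which fold newly made proteins, had a median log2 fold change of 0.01, a sign that flips without composition factors, and the 20 tRNA synthetase genes one of −0.02 with a mean of 0.02. Neither list was called by camera (adjusted p = 0.962 and 0.98), nor were the 7 ribosome-associated chaperone genes (−0.05, 0.249). The mating-type lists showed no exchange of type, as alpha-specific genes had a median of −0.11 (0.295) beside the fall of BAR1 and MFA1. Camera also called neither the ergosterol (−0.00), iron (−0.07), glycolysis (0.04), glucose-repressed (−0.14), unfolded protein response (−0.08), purine (−0.31), drug resistance (0.20), cell wall (0.03), histone (0.00), mitotic (0.05) and Yap1 (−0.02) lists nor the mitochondrially encoded genes (0.54) and the auxotrophic markers (0.18). Over all genes edgeR called 2 higher and 3 lower of 15 purine genes, 4 lower of 17 unfolded protein response genes, 1 higher and 2 lower of 5 auxotrophic markers, 2 lower of 22 glucose-repressed genes and 2 higher of 19 Yap1 genes. By fry without regard to direction these lists had adjusted p of 0.0136, 1.22e-05, 0.00138, 0.000794 and 0.00201. The ribosome-associated chaperone, histone and elongation factor lists held 0 genes called by edgeR. Their adjusted p by fry without regard to direction were 0.0327, 0.0281 and 0.0299. By fry with direction they were 0.353, 0.752 and 0.344, so that test did not call these lists. Over all genes edgeR also called 1 ergosterol gene lower and 1 tRNA synthetase gene higher. Of the lists above the glycolysis, cell wall, histone and mitotic medians change sign without composition factors, and the Yap1 list was tested in the direction opposite to its median.

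Among the 10 splits of the 6 libraries of a comparison, the split by group gave 382, 321 and 11 called genes by edgeR in the order of the report. The highest number in any other split was 0, so 1 of 10 gave as many. The absolute Hsf1 medians were 1.08, 0.84 and 0.28 against at most 0.42, 0.36 and 0.21 in other splits, again 1 of 10. The numbers of lists called by camera, adjusted within the comparison, were 19, 17 and 18, but 19, 20 and 18 lists were called in the other split with the most, and 2, 4 and 4 of the 10 splits gave as many as the split by group. With 10 splits the share cannot fall under 0.05. Each other split sets 2 libraries of a group and 1 of the other against the rest. It thus keeps part of the group difference and adds the rest to the spread within its sides. Lower gene counts and Hsf1 medians in the other splits follow from this wherever the groups differ. The numbers of genes, the Hsf1 medians and the numbers of lists therefore decide nothing here.

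Few genes were called between the construct strain and the wild type, and the spread of the construct libraries leaves room for changes that were not called. Genes were called in the deletion without 1 wild-type library, and that library was used to measure what remained of the change in each construct library. Without AIM29, ZPR1, tK(UUU)K and YKR075C, which are set by the genotype or lie beside AIM29, the mean share was 12.5%, 4.30% and 13.6% in replicates 1, 2 and 3, which argues against changes as large as in the deletion hidden by spread in these genes as a set. A smaller change in the same direction may remain but could not be judged, since the share ran from 1.91% to 14.8% over the 9 pairs of libraries with an SD of 4.67 (9.44% to 20.2% with those genes). The direction of the deletion change was seen in 75.9% of the 382 genes. A simulation of a construct strain equal to the wild type gave 62.9% to 69.5%, above 50% because the wild-type libraries are shared. That simulation drew all groups with 1 spread per gene, unlike the libraries, so its range may not hold for these data.

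The Hsf1 targets lay above the wild type in the construct strain by a median of 0.07, 0.37 and 0.24 in replicates 1, 2 and 3, and the amino acid synthesis list by 0.13, −0.22 and −0.00. The difference from the wild type was related to gene length, from annotated start to end (Spearman 0.12, −0.20 and 0.13 across genes). Removing that trend left Hsf1 medians of 0.08, 0.37 and 0.25 with a mean of 0.233, which argues against it. A remaining share common to both lists could not be judged: Hsf1 minus amino acid synthesis was −13.0 percentage points of the deletion change in replicate 1, and 68.3 and 23.4 in the others. That Hsf1 targets may stay raised while amino acid synthesis genes do not is a hypothesis that rests on replicates 2 and 3, the libraries with the lowest quality weights.

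Reads on tK(UUU)K and YKR075C were higher in both strains without AIM29. The other 7 tK(UUU) features together rose only 1.27-fold in the deletion and the remaining tRNA features 1.30-fold, which argues against shared reads or a general gain of tRNA. YKR075C was 0.31 ± 0.11 (log2, SE) higher in the construct strain than in the deletion, which argues against a response that the construct turned back. A change of transcription at the replaced locus is a candidate explanation that stays open, and so are reads from the sequence put in place of AIM29, which is not given in the sources used here. The test looked for a rise of YKR073C too, although such a change can act on 1 side alone, and that gene has few counts and did not pass the test, with a lowest log2 fold change of 0.66.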
